A study of Mus musculus with 8 samples.

How the data were processed

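B220+ B cells were taken from mouse spleens by magnetic depletion of CD43-bearing cells, and their RNA was sequenced in 8 libraries, 2 in each of 4 groups. The mice carried floxed copies of Kmt2d, the gene of a histone H3 lysine 4 methyltransferase also named MLL4. KO mice also carried the Cd19-Cre recombinase gene, which acts in B cells, and WT mice did not. Resting cells were compared with cells cultured for 3 days in RPMI medium containing 10% serum with lipopolysaccharide (LPS, 25 ug/ml), interleukin 4 (IL-4, 5 ng/ml) and an antibody to CD180 (0.5 ug/ml). Per the labels' protocols, RNA was purified with TRIzol and an RNeasy kit, libraries were made with the TruSeq RNA kit version 2, and reads of 50 bp were single or paired. The series design text gives n = 3 per state, whereas 4 resting and 4 stimulated libraries were deposited.

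The deposited values are counts of reads per Ensembl gene, 1 file per library, with no scaling per the labels. The submitters' processing notes name CASAVA 1.8.2, HTSeq 0.6.0 and the genome build mm10, without saying what each was used for. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. Reads from overlapping or antisense genes, and from near-identical copies such as the alpha and beta globin genes, can therefore have been shared or lost in ways that the files do not show. Each file held 43309 gene identifiers and 5 closing lines of reads given to no gene, 3 of them at 0. The other 2, for reads outside all genes (14.2% to 23.9% of a file) and ambiguous reads (2.6% to 3.6%), stayed out of library sizes and tests. Symbols and coordinates came from the GENCODE vM21 annotation of the same build (GRCm38), in which 42425 identifiers (98%) were found. No gene of the mitochondrial chromosome was present, so that measure of RNA quality was not available.

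Libraries were grouped by the genotype and cell state in their labels. Replicates were numbered in the order of deposition, so a shared number does not mark a shared animal or day, and no pairing was used. Counts were scaled by the trimmed mean of M-values (TMM), and genes were filtered with filterByExpr in edgeR 4.0.16 (minimum count 10, minimum total count 15), which left 17781 genes. Values per library are TMM-scaled counts relative to the library total (CPM), given as mean ± SD with n = 2. The quasi-likelihood F-test of edgeR was applied to a model with a mean for each of the 4 groups (4 residual degrees of freedom). Its contrasts were KO against WT in resting and in stimulated cells, stimulated against resting in WT and in KO cells, and the difference between the genotype contrasts of both states. KO against WT over both states was tested in a model with terms for genotype and state (5 residual degrees of freedom). Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested passed, with no fold threshold. The common dispersion was 0.0272, a biological coefficient of variation of 0.165. The p-values measure the spread between these libraries, and with 2 libraries per group they carry no wider sampling of animals.

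The comparisons, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. Of 39 lists of pathway genes, B cell subset markers and markers of other cell types, 534 of 547 members were found among the gene symbols, and 37 lists had enough tested members for a list test. That test was camera in limma 3.58.1 at an inter-gene correlation of 0.01, adjusted over the lists of a comparison, with the result at an estimated correlation beside it. The number of members that passed is given over all genes tested and, where it differs, adjusted over the list alone. Named genes were Kmt2d and Cd19 as label checks, the 10 largest rises and 10 largest falls of each comparison, up to 4 members of each list with the smallest adjusted p, the reported Kmt2d targets and the markers of other cell types that passed. The largest changes were taken from genes that passed, reached a mean of 5 CPM in the higher group and had no overlap between the libraries of both groups, leaving out predicted genes and immunoglobulin and T cell receptor segments. Genes named for KO against WT over both states could still overlap between KO and WT libraries of different states, as Trim30d did. For the difference between states, no separation of the libraries was required. In both of these comparisons the mean of 5 CPM was required of the highest of the 4 groups. Genes named outside this rule are marked as chosen after their values were seen. Where a group had no counts, the fold is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with its 95% counting interval. Such floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

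The tests were first run on simulated counts drawn from the means and sizes of the real libraries, with 50 genes changed at each of 4 fold sizes among 17781. In the stimulated genotype comparison edgeR recovered 10% of genes changed 1.5-fold, 58% of those changed 2-fold, 84% at 4-fold and 92% at 8-fold, with 15 false calls among 17581 unchanged genes. In the resting genotype comparison the shares were 12%, 46%, 78% and 82%, with 16 false calls. As numbers of genes, 5, 29, 42 and 46 were recovered in the stimulated comparison and 6, 23, 39 and 41 in the resting one. For the difference between states they were 0, 11, 29 and 43, with 15 false calls. In each of these comparisons the false calls made up a larger share of all calls than the adjusted p threshold. Camera called a set of 20 genes raised 2-fold in each of the 6 comparisons at the preset correlation, and in all but the difference between states at an estimated one (adjusted p = 0.0682 there). 0 of the 20 unchanged sets was called in any comparison by either setting. Each gene was drawn independently, so these sets cannot show how often the preset correlation calls unchanged lists whose members move together. In the stimulated genotype comparison the interferon response list had an estimated correlation of 0.683.

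The alternatives tried were other scalings (relative log expression, upper quartile, library totals), no filter or a stricter one (1 CPM in 4 libraries), a fold threshold, the DESeq2 1.42.0 Wald test, limma-voom, leaving out the immunoglobulin genes, fitting only the 4 libraries of a comparison and leaving out each library in turn. Another 3 were added after seeing the data, namely thinning every library to the smallest total, leaving out the genes of chromosomes X and Y, and leaving out both resting libraries numbered 1. Computing used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No library was left out of the comparisons.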

Results

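RNA was sequenced from splenic B220+ B cells of mice with a B cell deletion of Kmt2d (KO, Kmt2d floxed with Cd19-Cre) and of floxed mice without Cre (WT). Each of the 4 groups, resting WT, resting KO, stimulated WT and stimulated KO, held 2 libraries. Stimulated cells had been cultured for 3 days with LPS, which engages Toll-like receptor 4, with IL-4 and with an antibody to CD180, a B cell surface relative of the Toll-like receptors. The title of the series asks how gene expression in WT and Kmt2d-deficient B cells compares before and after that stimulation. Reads counted in genes came to 48083944 and 49606554 in the stimulated KO libraries over the genes tested, 50536978 and 61436937 in stimulated WT, 26467763 and 24863201 in resting KO, and 27646175 and 23880283 in resting WT. Reads outside all genes made up 14.2% to 15.6% of the stimulated files and 18.7% to 23.9% of the resting ones, and reads that fitted more than 1 gene a further 3.5% to 3.6% and 2.6% to 2.9%. Replicate libraries differed by more than counting error (chi-square per degree of freedom 19.9 to 50.8), with a Pearson r of log2 CPM across genes of 0.990 to 0.996 within groups. The first principal component, which separated the resting from the stimulated libraries, carried 86.1% of the variance, and the second carried 4.8%.

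Kmt2d (ENSMUSG00000048154, chromosome 15, 98831669 to 98871204, mm10), the targeted gene, was read at 235 and 248 CPM in the stimulated KO libraries and at 263 and 221 CPM in stimulated WT. In resting cells it was read at 678 and 628 CPM in KO and at 593 and 572 CPM in WT, a log2 fold change of 0.16 (SE 0.13, edgeR adjusted p = 0.625). The deletion removes only some exons, so a count over the whole gene checks nothing about the genotype labels. Cd19 (ENSMUSG00000030724, chromosome 7, 126408450 to 126414889), the gene into which Cre is inserted and which encodes a co-receptor of the B cell receptor, was lower in each KO library than in each WT library of its state. In stimulated cells Cd19 fell from 1116 ± 293 CPM in WT to 567 ± 9.66 CPM in KO (SD, n = 2 each, log2 fold change -0.98, SE 0.18, edgeR adjusted p = 0.0185). In resting cells it was 1630 ± 2.79 CPM in WT and 878 ± 51.1 CPM in KO (log2 fold change -0.89, SE 0.18, adjusted p = 0.0901). Xist, transcribed from the inactive X chromosome of females, was read at 2170 to 3370 CPM in the 4 resting libraries and at 2970 CPM in stimulated WT 1. It was read at 2.08, 2.56 and 2.86 CPM in stimulated KO 1, stimulated KO 2 and stimulated WT 2. The Y-linked gene Ddx3y stood at 153, 149 and 99.6 CPM in those last 3 libraries and at 0.355 CPM or less in the others. By these transcripts stimulated WT 1 was of the same sex as the 4 resting libraries, and the other 3 stimulated libraries were of the other sex.

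**Figure D1:**
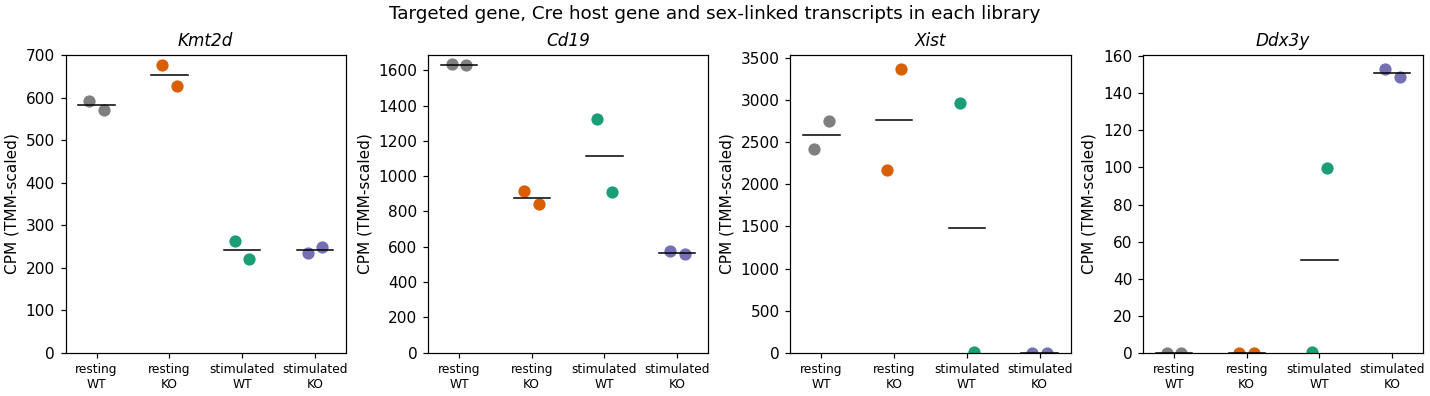
Each point is a library and each line a group mean of 2 libraries, in TMM-scaled CPM, for the targeted gene, the Cre host gene and transcripts of the X and Y chromosomes. Cd19 lay lower in KO than in WT in both states, while Kmt2d stood at 242 CPM in both stimulated groups, and Xist was high in the resting libraries and in stimulated WT 1.

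The effect of the Kmt2d deletion in activated B cells was asked of stimulated KO against stimulated WT, a contrast that also holds the presence of Cre and its insertion into Cd19. Of 22 interferon response genes 14 fell (median log2 fold change -1.89, camera adjusted p = 2.28e-18, and adjusted p = 0.466 with an estimated correlation). Without stimulated WT 1 the median was -1.05 and 2 passed. Irf7, a transcription factor of the interferon system, fell from 65.2 ± 55.5 CPM in WT to 6.75 ± 3.3 CPM in KO (n = 2 each, log2 fold change -3.27, SE 0.59). The antiviral genes Mx1 (-3.49, SE 0.60), Oas2 (-3.72, SE 0.73) and Rtp4 (-3.38, SE 0.71) fell with it. Of 16 migration and adhesion genes 3 fell, among them those of the integrin chains Itgal (134 ± 19.7 against 320 ± 13.6 CPM, log2 fold change -1.26, SE 0.14) and Itgb7 (-2.21, SE 0.29). The chemokine receptor gene Ccr6 was the third (-1.28, SE 0.19, camera adjusted p = 5.2e-04 for the list, and adjusted p = 0.466 with an estimated correlation). Spn, which encodes the sialoglycoprotein CD43, fell too (-2.04, SE 0.29). Both Itgal and Spn lie near Cd19 on chromosome 7. Of 14 p53 targets 4 rose (camera adjusted p = 4.78e-05, and adjusted p = 0.466 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 156 ± 21.3 against 71.1 ± 13.6 CPM (log2 fold change 1.13, SE 0.16). Rgs13, a regulator of G protein signalling known from germinal centre B cells, rose from 0.14 ± 0.03 to 20.8 ± 0.478 CPM (log2 fold change 7.17, SE 0.47). The chemokine gene Ccl22 rose from 907 ± 29.4 to 3325 ± 584 CPM (log2 fold change 1.87, SE 0.18).

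In all, 861 of 17781 genes differed between stimulated KO and WT cells, 351 higher and 510 lower in KO (edgeR, adjusted p under 0.05), and 607 of them by at least 2-fold. The largest rise was that of Myh7, a cardiac myosin heavy chain gene, at 6.39 ± 0.5 CPM in KO and without counts in WT, at least 240-fold higher against a floor of 3 counts over the WT group. Next came Rgs13, the matrix link protein gene Hapln1 (log2 fold change 4.79, SE 0.59), the protease gene Pappa2 (4.25, SE 0.65) and the purine receptor gene P2ry1 (4.18, SE 0.29). They were followed by Xkr6 (4.04, SE 0.31), Lrrn3 (3.47, SE 0.52), the connexin gene Gja1 (3.30, SE 0.39), Sytl2 (3.27, SE 0.30) and Smo, the transducer of Hedgehog signals (3.24, SE 0.20). The largest falls were those of Atp6v0e2, a subunit gene of the vacuolar proton pump (-6.66, SE 0.45), the NKG2D ligand gene H60b (-4.26, SE 0.30), Zfp541 (-3.77, SE 0.63), Oas2, Mx1 and Rtp4. Below them came the interferon-inducible Ifi214 (-3.27, SE 0.66), the actin-bundling gene Pls3 (-3.27, SE 0.26), Irf7 and Fut10 (-3.26, SE 0.35). Without stimulated KO 2 the count was 129, with 69 higher and 60 lower, so the excess of lower genes was not kept. Without stimulated WT 1 it was 413 and without stimulated KO 1 it was 523, both with more lower than higher. Among the named genes 43 calls ended without stimulated KO 2, 26 without stimulated WT 1, 20 without stimulated KO 1 and 16 without stimulated WT 2, and none of these genes changed direction.

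Of the 22 interferon response genes 14 fell and 0 rose, and 20 fell when adjusted over the list alone (median log2 fold change -1.89, camera adjusted p = 2.28e-18, and adjusted p = 0.466 with an estimated correlation). Oasl2 (-2.89, SE 0.54) and Ifit3 (-3.02, SE 0.58) were further examples. The WT libraries stood apart from each other, with Irf7 at 104 CPM in stimulated WT 1 and 26 CPM in stimulated WT 2, against 9.09 and 4.41 CPM in the KO libraries. Without stimulated WT 1 the median was -1.05, with 21 of 22 members below 0 and 2 passing the test. Of 18 Toll-like receptor genes 2 fell, Irf7 and the DNA sensor Tlr9 (-0.90, SE 0.20), and 6 adjusted over the list alone (camera adjusted p = 0.00601, and adjusted p = 0.466 with an estimated correlation). Of 19 JAK-STAT genes only Stat2, which relays the interferon signal, fell (-0.70, SE 0.16), over all genes and adjusted over the list alone (camera adjusted p = 0.0116, and adjusted p = 0.466 with an estimated correlation). Without stimulated KO 2 the list p-values were 0.126 and 0.0616.

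**Figure D2:**
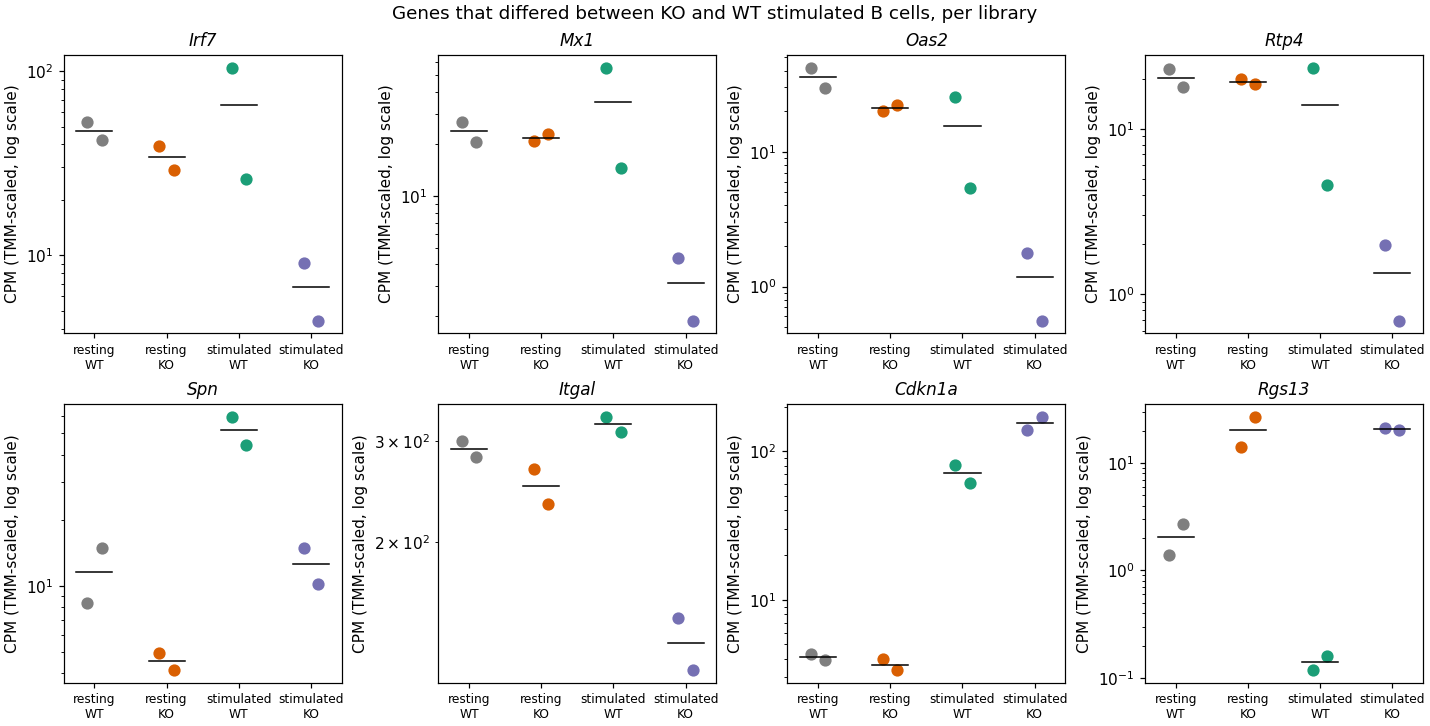
Each point is a library and each line a group mean of 2 libraries, in TMM-scaled CPM on a log axis, for 8 genes that passed the test in stimulated cells. The interferon genes Irf7, Mx1, Oas2 and Rtp4 were lower in both stimulated KO libraries than in both WT libraries, with Irf7 at 104 and 26 CPM in WT, and Rgs13 stood near 20 CPM in stimulated KO against 0.14 CPM in WT.

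Lists of B cell subsets and signalling were tested next. Of 18 B cell identity genes 3 fell, Cd19, whose fall goes with the Cre insertion that each KO mouse and no WT mouse carries, Ciita (-0.67, SE 0.14), the switch for MHC class II genes, and Bach2 (-0.51, SE 0.12), a repressor of plasma cell differentiation. In this list 7 fell when adjusted over the list alone (median -0.27, camera adjusted p = 5.6e-04, and adjusted p = 0.466 with an estimated correlation). Of 20 genes of B cell receptor signalling 4 fell, the scaffold gene Card11 (-1.19, SE 0.19), the phospholipase gene Plcg2 (-0.91, SE 0.15), the kinase gene Lyn (-0.62, SE 0.14) and Pik3cd (-0.63, SE 0.15). The count was 6 adjusted over the list alone (camera adjusted p = 8.66e-04, and adjusted p = 0.466 with an estimated correlation). Of 16 migration and adhesion genes Itgal, Itgb7 and Ccr6 fell and 0 rose, and the same number adjusted over the list alone (camera adjusted p = 5.2e-04, and adjusted p = 0.466 with an estimated correlation). Of 6 B-1 cell genes 3 fell, Spn, Itgam (-1.71, SE 0.37) and Cd5 (-3.15, SE 0.53), or 4 adjusted over the list alone (camera adjusted p = 2.88e-05, and adjusted p = 0.466 with an estimated correlation). Spn (from 127132232), Itgal and Itgam (from 128062640) lie near Cd19 (from 126408450) on chromosome 7. Whether the Cre insertion or the DNA around it contributed to their falls was not tested. Of 8 marginal zone genes 0 passed, and 6 fell when adjusted over the list alone (median -0.50, camera adjusted p = 0.0056, and adjusted p = 0.466 with an estimated correlation). Without stimulated KO 2 the marginal zone p-value was 0.140. The naive follicular list was not called (adjusted p = 0.0937), though 2 of its 14 members fell, Ighd (-1.68, SE 0.25), the constant region of IgD, and Bach2, and 3 adjusted over the list alone.

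Of 14 p53 targets 4 rose and 0 fell, and 6 rose when adjusted over the list alone (median 0.47, camera adjusted p = 4.78e-05, and adjusted p = 0.466 with an estimated correlation). They were Cdkn1a, Eda2r (2.67, SE 0.39), the death receptor gene Tnfrsf10b (0.66, SE 0.14) and Zmat3 (0.92, SE 0.16). Among 15 apoptosis regulators the pro-apoptotic Bcl2l11 fell (-0.93, SE 0.15) and the anti-apoptotic Bcl2 rose (0.56, SE 0.12), and 1 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.815). Among 18 NF-kB response genes the cytokine genes Tnf (-2.28, SE 0.22), Lta (-1.69, SE 0.27) and Ebi3 (-0.98, SE 0.16) fell and Il6 rose (0.65, SE 0.12), the same counts as adjusted over the list alone. The list had a median of 0.02 and a mean of -0.23, and the test pointed down without a call (camera adjusted p = 0.14). Of 12 genes of MHC class II antigen presentation Ciita and H2-DMb1 (-0.61, SE 0.14) fell, and 1 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.216). Tnf, Lta and H2-DMb1 lie in the MHC region of chromosome 17. There H2-Ea-ps, chosen after its values were seen, stood at 84.5 and 63.3 CPM in the stimulated WT libraries. It stood at 0.119 and 0.173 CPM in stimulated KO and did not pass (edgeR adjusted p = 0.056). Ccl22 rose as 1 of 10 IL-4 response genes, and 1 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.567). The immediate early gene Nr4a1 rose (1.23, SE 0.22), 1 of 14 in its list, with 2 adjusted over the list alone (camera adjusted p = 0.443). Cdkn1a rose and Cdkn2d fell (-0.63, SE 0.15) among 14 cell cycle inhibitors, the same counts as adjusted over the list alone (camera adjusted p = 0.744).

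Of 16 genes of H3K4 methyltransferase complexes only Paxip1, a subunit gene of the Kmt2c and Kmt2d complexes, fell (-0.81, SE 0.13), over all genes and adjusted over the list alone (camera adjusted p = 0.401). It was also the 1 member of 13 class switching genes that passed (camera adjusted p = 0.815), again the same count adjusted over the list alone. Of 5 reported Kmt2d targets 0 passed over all genes, and 1 fell when adjusted over the list alone (camera adjusted p = 0.338, and 0.909 with an estimated correlation). The values were -0.42 for Asxl1 (SE 0.12), -0.21 for Tnfrsf14 (SE 0.14), -0.14 for Arid1a (SE 0.12), -0.11 for Socs3 (SE 0.20) and -0.01 for Tnfaip3 (SE 0.12). That list may have been chosen partly on samples of this study and is no independent evidence of a direction. Lists of cell division and metabolism were not called, namely G2/M (adjusted p = 0.35), DNA replication (0.458), Myc and ribosome biogenesis (0.428), glycolysis (0.216), oxidative phosphorylation (0.815), cholesterol synthesis (0.428) and the unfolded protein response (0.781). Of their members 0 passed over all genes or adjusted over the list alone. Nor were CD40 and TNF receptor signalling (adjusted p = 0.216) and the plasma cell list (0.815), both with 0 members passing either way.

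Markers of other cell types moved in part with the genotype of stimulated cells. Of 10 T cell markers 3 fell, the kinase gene Lck (-1.42, SE 0.20), Cd3g and Cd5, and Cd8b1 rose (2.18, SE 0.49). The list had 5 falling and 1 rising when adjusted over the list alone (camera adjusted p = 0.00111, and adjusted p = 0.466 with an estimated correlation). Cd3g was 72.1-fold lower in KO (95% counting interval 19.6 to 601), and without stimulated KO 2 the list p-value was 0.0524. Lck stood at 81.2 ± 24.2 CPM in KO and 217 ± 43.7 CPM in WT, whereas the T cell genes Cd4, at 0.0594 and 0.0537 CPM, and Cd8a, at 0.157 and 0.0778 CPM, were near 0 in both. Among 13 macrophage markers Lyz2 rose (3.23, SE 0.58) from 0.0939 to 0.939 CPM and Cd68 fell (-1.13, SE 0.22), with 2 rising and 2 falling when adjusted over the list alone (camera adjusted p = 0.44). Among 7 dendritic cell markers the integrin gene Itgax, near Cd19 on chromosome 7, fell (-2.07, SE 0.45), 1 adjusted over the list alone (camera adjusted p = 0.374). The beta globin gene Hbb-bt stood at 1.19 CPM in KO and without counts in WT, at least 44.9-fold higher, as 1 of 9 erythroid markers, 1 adjusted over the list alone (camera adjusted p = 0.248). Of 3 NK cell and 5 platelet markers 0 passed over all genes (adjusted p = 0.44 and 0.589), and adjusted over the list alone 1 NK cell marker fell. Of 5 sex-linked transcripts 0 passed, and 1 was lower adjusted over the list alone (adjusted p = 0.401). Of 5 immature B cell genes Vpreb3, a chaperone gene of the immature receptor, fell (-1.55, SE 0.31), and 1 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.44). Rgs13 was the 1 of 11 germinal centre genes that rose, with 1 rising and 1 falling adjusted over the list alone (median -0.21, mean 0.27, camera adjusted p = 0.567). For Lcn2, the 1 neutrophil marker among the genes tested, the log2 fold change was -0.91 (SE 0.82).

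In resting cells the same genotype contrast asked what the Kmt2d deletion did before stimulation. The IgG1 constant region transcript Ighg1 rose from 14.0 ± 1.17 CPM in WT to 66.5 ± 16.9 CPM in KO (n = 2 each, log2 fold change 2.24, SE 0.19, edgeR adjusted p = 0.00718). Rgs13 rose from 2.04 ± 0.917 to 20.4 ± 9.03 CPM (log2 fold change 3.33, SE 0.37) and the phospholipase gene Plcd3 from 0.238 ± 0.0351 to 5.88 ± 1.48 CPM (4.60, SE 0.41). Itgb7 fell from 241 ± 32.7 to 80.5 ± 2.01 CPM (-1.58, SE 0.24), as did Il6ra, the receptor chain of interleukin 6 (-1.60, SE 0.24), and the stress kinase genes Mapk12 (-1.27, SE 0.17) and Mapk11 (-1.08, SE 0.15). Mapk12 (89130584 to 89140703) and Mapk11 (89142486 to 89149628) are neighbours on chromosome 15, so their falls need not be separate events.

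Here 46 genes differed, 34 higher and 12 lower in KO (edgeR), while 2256 had an unadjusted p under 0.05. The other large rises were those of Ndrg1 (2.15, SE 0.32), the centromere chaperone gene Hjurp (1.76, SE 0.22), Plekhg5 (1.55, SE 0.23), the alkaline phosphatase gene Alpl (1.47, SE 0.21) and Mroh2a (1.44, SE 0.22). To these came the mitochondrial carrier gene Slc25a13 (1.43, SE 0.17) and Ntng2 (1.24, SE 0.19). Hjurp (88262471 to 88277633) and Mroh2a (88226986 to 88262289) are neighbours on chromosome 1. The other large falls were those of Gpr146 (-1.22, SE 0.15), the phosphatase gene Dusp3 (-1.17, SE 0.15), the nucleotide transporter gene Slc17a9 (-1.13, SE 0.17), AI467606 (-1.10, SE 0.15), the tropomyosin gene Tpm3 (-1.01, SE 0.12) and Ehd4 (-0.91, SE 0.13). AI467606 (from 127091359) lies near Cd19 on chromosome 7. Tpm3 (from 90072649) lies near Il6ra (89864059 to 89913196) on chromosome 3. Whether regional differences between the mice account for calls of nearby genes was not tested here. The count was 2 without resting WT 2, 4 without stimulated KO 1, 4 without stimulated KO 2, 7 without resting KO 2, 22 without stimulated WT 1, 22 without stimulated WT 2 and 30 without resting KO 1. The balance of directions turned without resting WT 1, with 13 higher and 25 lower of 38, and without resting WT 2 the 2 genes were both lower. DESeq2 called 463 genes and limma-voom 14.

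In resting KO cells 1 of 20 G2/M genes rose over all genes, the spindle checkpoint gene Bub1b (17.2 ± 0.534 against 9.65 ± 0.0462 CPM, log2 fold change 0.83, SE 0.11). Of the 20 genes 12 rose when adjusted over the list alone (median 0.50, camera adjusted p = 3.17e-12, and adjusted p = 0.58 with an estimated correlation). Of 11 germinal centre genes Rgs13 rose, and 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 3.82e-04, and adjusted p = 0.58 with an estimated correlation). Of 13 class switching genes Ighg1 rose, 1 also adjusted over the list alone (camera adjusted p = 0.00377, and adjusted p = 0.651 with an estimated correlation). Of 14 plasma cell genes 0 passed and 3 rose adjusted over the list alone (camera adjusted p = 0.00406, and adjusted p = 0.651 with an estimated correlation). The joining chain gene Jchain had a log2 fold change of 2.28 (SE 0.46, adjusted p = 0.0962). Of 8 marginal zone genes 0 passed and 1 rose adjusted over the list alone (camera adjusted p = 0.00472, and adjusted p = 0.651 with an estimated correlation). Without resting WT 2 the p-values of the class switching and marginal zone lists were 0.0735 and 0.127, without resting KO 2 that of the plasma cell list was 0.152, and without resting KO 1 that of class switching was 0.0592. Aicda, the gene of the switching deaminase, differed more within genotypes than between them, at 229 and 18.4 CPM in the KO libraries and 202 and 8.87 CPM in the WT libraries.

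Further resting lists were called up with 0 members passing over all genes, each with a camera call that ended with an estimated correlation. They were Myc and ribosome biogenesis (adjusted p = 0.00317, and adjusted p = 0.732 with an estimated correlation) and glycolysis (0.0168, and adjusted p = 0.745 with an estimated correlation). So were oxidative phosphorylation and DNA replication (0.0221 each, and adjusted p = 0.75 with an estimated correlation). Adjusted over the list alone 1 glycolysis gene rose and 0 of the other 3 lists. CD40 and TNF receptor signalling was called down (0.00472, and adjusted p = 0.58 with an estimated correlation), with 2 of 18 genes falling adjusted over the list alone. Also down were naive follicular genes (0.00967, and adjusted p = 0.58 with an estimated correlation) and Toll-like receptor genes (0.0344, and adjusted p = 0.651 with an estimated correlation), with 0 each. Macrophage markers were called up (median 0.52, adjusted p = 0.00204, and adjusted p = 0.732 with an estimated correlation), with 0 of 13 passing either way. All 8 lost the call without 1 library or another. Without resting WT 1 the camera adjusted p was 0.0571 for CD40, 0.0571 for oxidative phosphorylation, 0.064 for DNA replication, 0.285 for Toll-like receptor genes and 0.63 for macrophage markers. Without resting WT 2 it was 0.146 for Myc, 0.0735 for glycolysis, 0.0736 for oxidative phosphorylation and 0.0502 for DNA replication. Without resting KO 1 it was 0.159 for DNA replication, 0.562 for glycolysis, 0.695 for oxidative phosphorylation and 0.0842 for macrophage markers, and without resting KO 2 it was 0.154 for naive follicular and 0.154 for Toll-like receptor genes. Libraries also differed in structured RNA, read from 10 small non-coding RNA genes chosen after their values were seen. These summed to 254 and 238 CPM in resting KO 2 and resting WT 1 against 13.4 and 9.98 CPM in resting KO 1 and resting WT 2. Of 16 migration and adhesion genes Itgb7 fell, and 2 rose and 3 fell adjusted over the list alone (adjusted p = 0.0634). Of 14 p53 targets Tnfrsf10b rose (1.23, SE 0.19), 1 also adjusted over the list alone (adjusted p = 0.133). The interferon list was not called in resting cells (median -0.21, adjusted p = 0.19, with 0 of 22 passing either way). Nor were the reported Kmt2d targets (adjusted p = 0.919, 0 of 5 passing either way) or the genes of H3K4 methyltransferase complexes (adjusted p = 0.795, 0 of 16 passing either way).

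**Figure D3:**
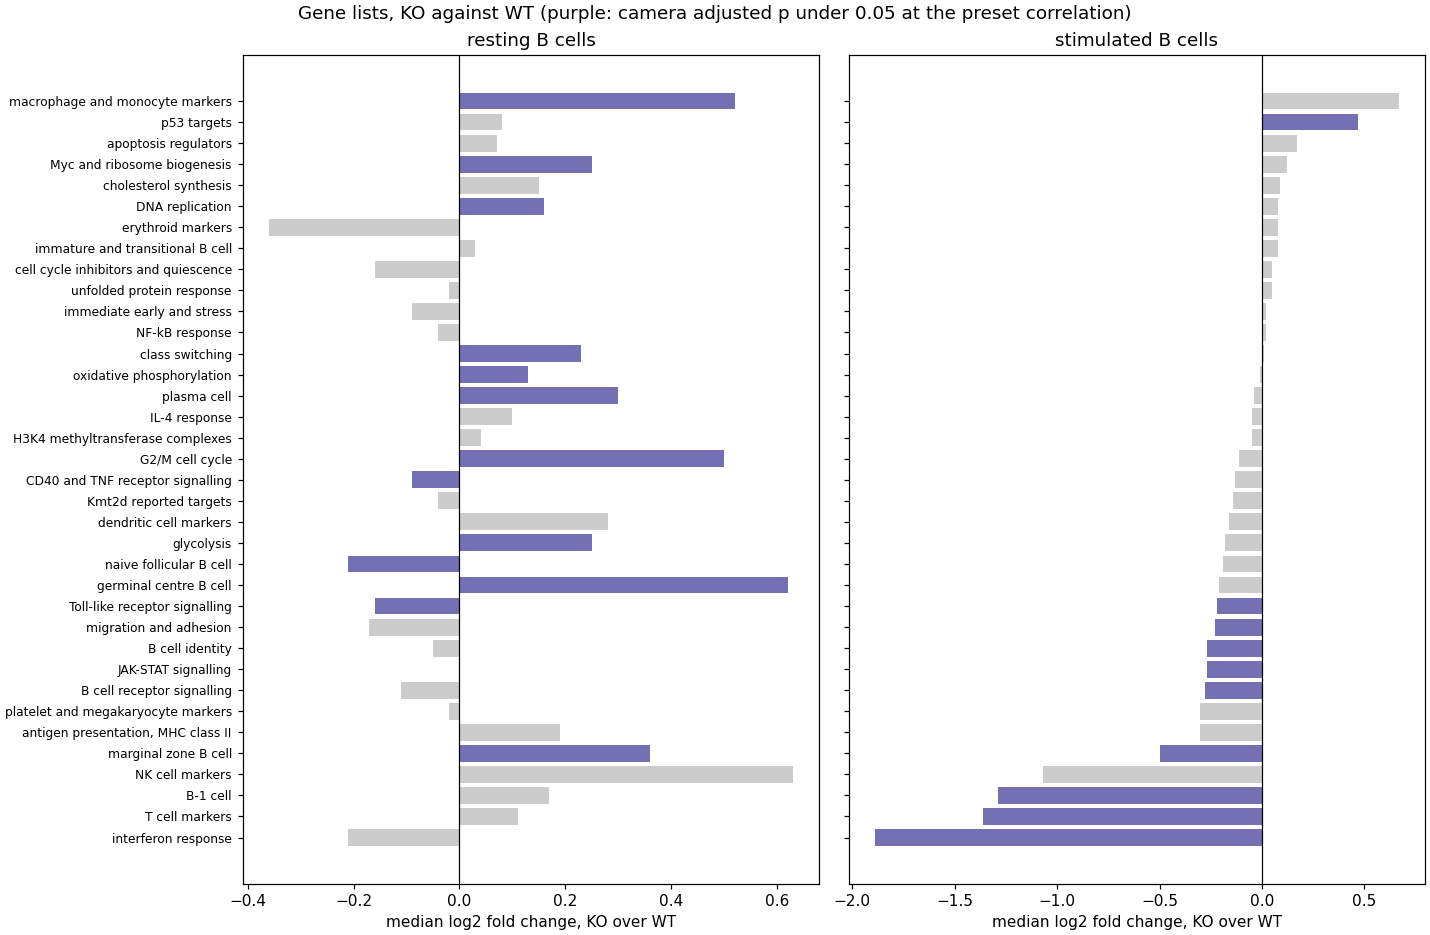
Bars show the median log2 fold change, KO over WT, of the tested members of each gene list in resting (left) and stimulated (right) cells, purple where camera called the list at the preset correlation, with a different axis scale in each panel. The interferon list stood at -1.89 in stimulated and -0.21 in resting cells, and the G2/M list at -0.11 and 0.50.

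Genotype was also compared over both states. Rgs13, Khdrbs3, Slc25a13, Tnfrsf10b, Azin2, Fmn2 and Tmem136 were higher in KO in both states, 7 genes against 0.671 expected of independent lists (Fisher's exact test, two-sided p = 3.74e-06). Itgb7, Gpr146 and Slc17a9 were lower in both, 3 against 0.344 (exact p = 0.00425). Both contrasts used the same estimate of spread for each gene, so the lists were not independent and these exact p-values can be too small. Tmem136 lies in the chromosome 9 region of neighbouring calls described under the other observations. Over both states 319 genes differed (172 higher and 147 lower in KO, edgeR), led by Trim30d (log2 fold change 5.02, SE 0.96), Rgs13 (4.87, SE 0.71), Hapln1 (4.65, SE 0.66), P2ry1 (3.94, SE 0.38) and Gja1 (2.97, SE 0.47). Then came Smo (2.93, SE 0.31), Reln (2.75, SE 0.33), the p53 target Perp (2.73, SE 0.32), Khdrbs3 (2.58, SE 0.32) and Gad1 (2.50, SE 0.38). The largest falls were those of Slamf9 (-1.99, SE 0.36), Cpne5 (-1.90, SE 0.26), the adaptor gene Scimp (-1.90, SE 0.35) and Itgb7 (-1.85, SE 0.21). Next were Stac2 (-1.78, SE 0.32), Spn (-1.72, SE 0.24), Cdkl1 (-1.62, SE 0.28), the adhesion gene Ceacam1 (-1.60, SE 0.26), Itih5 (-1.59, SE 0.21) and Crip3 (-1.59, SE 0.33). Cd19 fell as well (-0.94, adjusted p = 0.0149). Some of these genes were hardly read in 1 of the states. Hapln1, P2ry1, Gja1, Perp and Smo stood at 0.04, 0.12, 0.16, 0.2 and 0.36 CPM in resting KO, and Cdkl1, Crip3 and Cpne5 at 0.049, 0.0984 and 0.108 CPM in stimulated KO. Trim30d was not evenly high, at 34.9 and 23.0 CPM in stimulated KO and 39.6 CPM in resting KO 2 but at 0.832 CPM in resting KO 1. That last value lay below the 1.28 CPM of stimulated WT 1. Within each state both KO libraries lay above both WT libraries for Trim30d. Camera called 13 lists, 4 up and 9 down, and 0 with an estimated correlation. Among them were interferon response (0 of 22 passing, 6 lower adjusted over the list alone, median -1.19, adjusted p = 6.58e-09, and adjusted p = 0.668 with an estimated correlation) and p53 targets (2 of 14 higher, 6 adjusted over the list alone, median 0.39, adjusted p = 7.05e-04, and adjusted p = 0.277 with an estimated correlation). The count was 1 without stimulated KO 2, 30 without stimulated WT 2, 35 without stimulated KO 1, 85 without stimulated WT 1, 120 without resting KO 2 and 168 without resting WT 2. The balance of directions turned without resting WT 1 (153 higher and 156 lower), with a stricter filter (93 and 101), by DESeq2 (444 and 520) and as the average of the 2 genotype contrasts (278 and 327), and the 1 gene without stimulated KO 2 was lower. Resting and stimulated folds correlated across genes at r = 0.162, where genes are not independent replicates.

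The difference between the genotype effects of both states was tested as an interaction. The KO to WT ratio of Ighg1 was lower after stimulation than at rest (log2 difference -2.59, SE 0.26), with 2044 ± 44 CPM in KO and 2600 ± 231 CPM in WT after stimulation. Tnf (-2.23, SE 0.30), H60b (-3.91, SE 0.39), Pls3 (-3.39, SE 0.37) and Plcd3 (-3.82, SE 0.51) also had lower KO to WT ratios after stimulation. So did the polarity gene Pard6g (-2.71, SE 0.28), the phagocytosis checkpoint gene Sirpa (-2.57, SE 0.39), Pacsin1 (-2.01, SE 0.29), the zinc transporter gene Slc39a4 (-2, SE 0.29) and the ribosomal protein gene Rpl35a (-3.18, SE 0.46). Higher ratios after stimulation were found for Xkr6 (4.16, SE 0.40), Kctd14 (3.59, SE 0.50), Crisp3 (2.89, SE 0.36) and the kinase gene Plk2 (2.16, SE 0.24). They were also found for Afap1 (1.97, SE 0.25), the sialyltransferase gene St3gal1 (1.51, SE 0.19), the ceramidase gene Asah1 (1.16, SE 0.17), Gprasp1 (1.05, SE 0.14) and Ccnb1ip1, which had no counts in stimulated WT. The test passed 40 genes, 15 with a higher and 25 with a lower ratio (edgeR). It passed 8 without stimulated KO 2, 14 without both resting libraries numbered 1 and 91 without stimulated WT 2. The balance of directions turned without stimulated KO 2 (7 higher and 1 lower), without resting KO 2 (21 and 14), without resting WT 1 (17 and 12) and narrowly without resting WT 2 (16 and 15). Camera called 9 lists, all toward lower ratios after stimulation and 0 with an estimated correlation. First came interferon response (0 of 22 passing, 14 lower adjusted over the list alone, median -1.76, adjusted p = 2.35e-13, and adjusted p = 0.706 with an estimated correlation). Next was G2/M (1 of 20 lower, 9 adjusted over the list alone, median -0.60, adjusted p = 1.38e-10, and adjusted p = 0.706 with an estimated correlation).

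Stimulation was compared with rest in each genotype, to see what changed over 3 days of culture with LPS, IL-4 and anti-CD180. No group was labelled as cultured for 3 days without these stimuli, so effects of culture and of the stimuli cannot be told apart. In WT the lymph node homing receptor gene Sell fell from 1621 ± 19.3 to 10.2 ± 0.184 CPM (n = 2 each, log2 fold change -7.31, SE 0.20). The egress receptor gene S1pr1 fell from 551 ± 16.2 to 2.54 ± 0.211 CPM (-7.76, SE 0.15). Rises were found for the chemokine gene Ccl22 (5.42 ± 1.15 to 907 ± 29.4 CPM, 7.38, SE 0.23) and the cytokine signalling inhibitor Cish (7.43, SE 0.15). They were also found for the IgG1 transcript Ighg1 (14.0 ± 1.17 to 2600 ± 231 CPM, 7.53, SE 0.24) and for the division gene Bub1b (4.61, SE 0.12) and the sterol synthesis gene Hmgcs1 (4.27, SE 0.16). In KO the values were -7.14 for Sell (SE 0.20), -7.50 for S1pr1 (SE 0.15), 8.76 for Ccl22 (SE 0.24) and 3.63 for Bub1b (SE 0.11). The rise of Bub1b was smaller in KO by the interaction test (-0.97, SE 0.15, adjusted p = 0.0431), and the difference for Ccl22 did not pass (1.38, SE 0.26, adjusted p = 0.0861).

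In WT 11883 genes differed by state, 5971 higher and 5912 lower, and in KO 12036, 6036 higher and 6000 lower (edgeR), with 10283 called in both in the same direction and 40 in opposite directions. Folds correlated at r = 0.917 across genes, which are not independent replicates. The largest WT rises included the chemokine receptor genes Ccr4 (at least 1480-fold, 88.5 ± 15.9 CPM) and Gpr15 (log2 fold change 11.93, SE 0.26). Others were Gprin3 (at least 496-fold), Mgarp (at least 263-fold), Vldlr (at least 203-fold), the agouti gene a (at least 184-fold), Atp6v0e2 (at least 170-fold) and Thy1 (3350-fold, 95% counting interval 1150 to 16200). The largest KO rises included Ccr4 (at least 2460-fold), Ido2 (at least 758-fold), Gprin3 (at least 715-fold), Dnah12 (at least 604-fold), Vldlr (at least 558-fold), Adamts20 (at least 439-fold) and Stc2 (at least 380-fold). The Y-linked Uty (at least 481-fold and 1060-fold) and Eif2s3y (at least 1600-fold and 2990-fold) stood among them in WT and KO, which goes with the sex of the libraries, as does Ddx3y in KO (at least 2520-fold). The largest falls in KO included Icosl, the ligand of a T cell costimulator (-13.33, SE 0.53) and Cxcl9 (at least 360-fold lower). Further falls were those of Apol7c (4360-fold lower, 95% counting interval 782 to 172000) and the structured RNA gene Rmrp (at least 575-fold lower), which was unevenly read in the resting libraries. State was inseparable from library series, since the titles of the resting and stimulated libraries are of different kinds, and mostly from sex.

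The list tests for stimulation called 21 lists in WT and 18 in KO, and with an estimated correlation only migration and adhesion and IL-4 response in KO held (adjusted p = 0.0345 each). All 20 G2/M genes rose in both genotypes (median 4.44 in WT, camera adjusted p = 2.54e-41, and adjusted p = 0.0679 with an estimated correlation). So did all 18 cholesterol synthesis genes (3.10, adjusted p = 3.69e-25, and adjusted p = 0.0679 with an estimated correlation). Among these were Hmgcr, the rate-limiting enzyme of the pathway (3.06, SE 0.11), Cyp51 (3.66, SE 0.13) and Idi1 (4.62, SE 0.18). Except where given, the counts for stimulation were the same adjusted over the list alone. Of 23 DNA replication genes 20 rose, for example Rrm2 (3.64, SE 0.18) and Tyms (3.37, SE 0.17) (adjusted p = 1.34e-12, and adjusted p = 0.288 with an estimated correlation). Of 15 glycolysis genes 14 rose in WT, 15 adjusted over the list alone, led by the lactate exporter Slc16a3 (6.83, SE 0.23) and Hk2 (3.83, SE 0.15) (adjusted p = 1.66e-13, and adjusted p = 0.186 with an estimated correlation). Of 10 IL-4 response genes 7 rose in each genotype, 8 in KO adjusted over the list alone, with Nfil3 (7.32, SE 0.18) and Batf (3.12, SE 0.13) beside Ccl22 and Cish (adjusted p = 3.31e-12, and adjusted p = 0.0614 with an estimated correlation). Of 19 JAK-STAT genes 12 rose and 4 fell in WT, with Stat5a (3.90, SE 0.15) and the feedback genes Socs2 (5.26, SE 0.21) and Socs1 (3.90, SE 0.23) among them (adjusted p = 5.27e-05, and adjusted p = 0.251 with an estimated correlation). Of 14 p53 targets 10 rose and 1 fell in WT (adjusted p = 0.00174, and adjusted p = 0.308 with an estimated correlation). In KO 12 rose and 1 fell (adjusted p = 1.61e-04, and adjusted p = 0.246 with an estimated correlation). Of 13 class switching genes 9 rose and 1 fell in WT, with Msh6 at 1.8 (SE 0.11) (adjusted p = 7.57e-04, and adjusted p = 0.288 with an estimated correlation). Myc and ribosome biogenesis was called in WT and not in KO (14 of 19 rose and 1 fell, 14 and 2 adjusted over the list alone, adjusted p = 0.0148, and adjusted p = 0.584 with an estimated correlation). The NF-kB response list (11 of 18 rose and 4 fell, adjusted p = 0.0157, and adjusted p = 0.294 with an estimated correlation) and the B-1 cell list (4 of 6 rose and 1 fell, adjusted p = 0.0212, and adjusted p = 0.39 with an estimated correlation) were too. In KO their p-values were 0.0583, 0.0528 and 0.297. In the interaction the B-1 list was called (adjusted p = 1.47e-07, and adjusted p = 0.706 with an estimated correlation) while the other 2 were not (0.239 and 0.193).

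Of 14 immediate early genes 13 fell and 1 rose in WT, with Fosb (-11.94, SE 0.29), Fos (-8.44, SE 0.31) and Dusp1 (-5.47, SE 0.13) lowest (camera adjusted p = 7.71e-14, and adjusted p = 0.0679 with an estimated correlation). Of 16 migration and adhesion genes 12 fell in WT (adjusted p = 1.38e-10, and adjusted p = 0.0679 with an estimated correlation). In KO 14 fell, 15 adjusted over the list alone (adjusted p = 4.47e-12), for example Cxcr4 (-2.97, SE 0.16 in WT). Of 14 naive follicular genes 11 fell and 2 rose in WT, with Ighd (-4.57, SE 0.28) and the quiescence factor Klf2 (-5.32, SE 0.38) among them (adjusted p = 4.29e-08, and adjusted p = 0.0853 with an estimated correlation). Of 8 marginal zone genes 6 fell in WT, led by the complement receptor Cr2 (-6.40, SE 0.26) and Cd1d1 (-3.96, SE 0.15) (adjusted p = 8.77e-05, and adjusted p = 0.288 with an estimated correlation). Of 18 B cell identity genes 15 fell and 1 rose in WT, with Bank1 (-3.90, SE 0.32) and Blk (-2.26, SE 0.15) among them (adjusted p = 6.24e-06, and adjusted p = 0.288 with an estimated correlation). Of 20 B cell receptor genes 16 fell and 1 rose, with Syk (-3.30, SE 0.15) lowest among those named (adjusted p = 1.94e-04, and adjusted p = 0.308 with an estimated correlation). Of 12 MHC class II genes 8 fell and 2 rose, 9 and 2 adjusted over the list alone (adjusted p = 0.00742, and adjusted p = 0.352 with an estimated correlation). Of 18 Toll-like receptor genes 12 fell and 2 rose, 13 and 2 adjusted over the list alone, with Tlr4, the receptor of the LPS used, at -3.14 (SE 0.30) (adjusted p = 0.0145, and adjusted p = 0.308 with an estimated correlation). Kmt2d itself fell in WT (-1.27, SE 0.13) and in KO (-1.43, SE 0.13). It belonged to the 7 of 16 genes of H3K4 methyltransferase complexes that fell in each, with 6 rising in WT and 3 in KO (camera adjusted p = 0.554 and 0.297).

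Markers of other cell types went both ways with stimulation. Of 9 erythroid markers 8 fell in both genotypes (camera adjusted p = 2.58e-05 in WT, and adjusted p = 0.352 with an estimated correlation). The beta globin gene Hbb-bs stood at 1176 ± 933 CPM in resting WT and without counts in stimulated WT, at least 44200-fold lower. Of 13 macrophage markers 10 fell and 2 rose in WT (adjusted p = 1.08e-04, and adjusted p = 0.415 with an estimated correlation). Slc40a1 was at least 1190-fold and Vcam1 at least 1200-fold lower, and the complement genes C1qa, C1qb and C1qc were at least 555-fold, 755-fold and 615-fold lower. The colony stimulating factor receptor gene Csf1r fell from 19 ± 11.7 to 0.0376 ± 0.0305 CPM in WT (-8.94, SE 0.73). Among T cell markers Cd8a (-7.27, SE 0.43) and Cd4 (-6.11, SE 0.62) fell and Lck rose (2.13, SE 0.21) in WT, 3 of 10 falling and 4 rising (adjusted p = 0.564). Other markers rose in WT, such as the macrophage genes Mpeg1 (0.98) and Cd68 (1.01), the platelet integrin gene Itgb3 (1.16) and the dendritic cell gene Zbtb46 (1.97). The dendritic, NK cell and platelet lists were not called (adjusted p = 0.564, 0.129 and 0.181 in WT). The dendritic cell marker Clec9a was at least 329-fold lower in WT and at least 359-fold lower in KO.

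**Figure D4:**
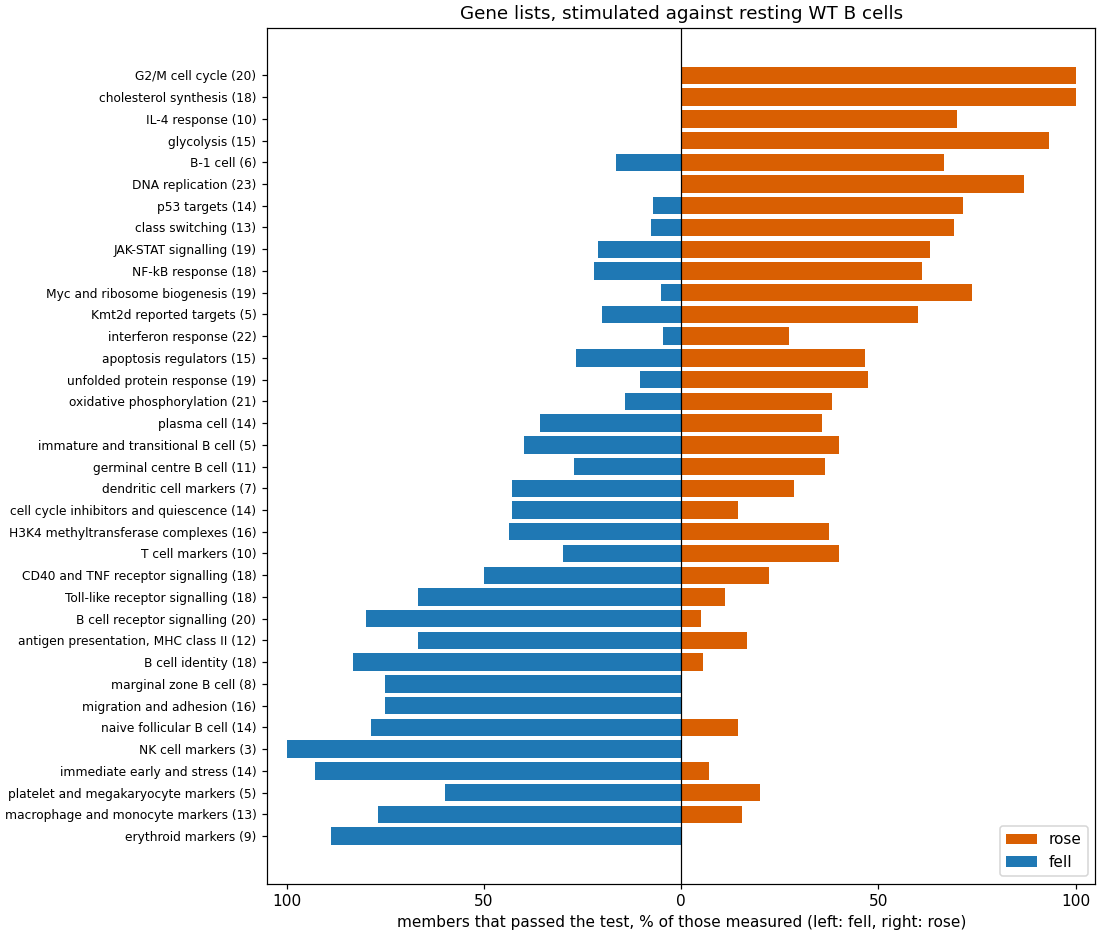
Bars show, for stimulated against resting WT cells, the percentage of measured members of each gene list that passed the edgeR test, falls to the left and rises to the right, with the number of members in brackets. All 20 G2/M genes and all 18 cholesterol synthesis genes rose, and 8 of 9 erythroid markers fell.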

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

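Of the tests below, those of depth, of sex, of the interferon genes and of genes read in only 1 library of a group were chosen only after the result was seen.

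KO to WT differences were tested between states, and 40 genes differed by edgeR. The log2 difference of the KO to WT ratio, stimulated minus resting, was negative for Pls3 (-3.39), Plcd3 (-3.82), Sirpa (-2.57), Pacsin1 (-2.01), Pard6g (-2.71), Rpl35a (-3.18), Slc39a4 (-2), H60b (-3.91), Ighg1 (-2.59) and Tnf (-2.23). It was positive for St3gal1 (1.51), Plk2 (2.16), Crisp3 (2.89), Afap1 (1.97), Asah1 (1.16), Xkr6 (4.16), Gprasp1 (1.05) and Kctd14 (3.59). For Ccnb1ip1 the fitted value was 9.08, which is no bound because stimulated WT had no counts. The camera adjusted p for the difference between states was 2.35e-13 for interferon response, 1.38e-10 for G2/M, 1.47e-07 for B-1 cell, 8.39e-07 for marginal zone, 0.00266 for glycolysis, 0.00266 for T cell markers, 0.0245 for class switching, 0.0419 for MHC class II and 0.0479 for JAK-STAT, and with an estimated correlation 0 of these 9 lists held (adjusted p = 0.706 to 0.714). Of these calls 5 ended when 1 library was left out, at up to 0.438 for JAK-STAT (without resting KO 1), 0.314 for MHC class II (without stimulated WT 1), 0.143 for class switching (without resting WT 2), 0.161 for glycolysis (without stimulated WT 2) and 0.0654 for T cell markers (without stimulated KO 2).

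More genes differed by genotype in stimulated cells (861) than in resting cells (46). Thinning every library to the smallest total left 665 stimulated against 42 resting calls, which argues against depth as the whole source. Leaving out stimulated WT 1, the 1 stimulated library with high Xist, left 413 against 22, which argues against unequal sex as the whole source. The biological coefficient of variation of the resting libraries was 1.12 times that of the stimulated ones, too near 1 to tell whether spread could account for part of the difference. A larger effect of the deletion in stimulated cells stays open, as does the library series, which is confounded with state. Strain haplotypes that differ between the mice stay open too, and were not tested for this count. H2-Ea-ps, Trim12a and Zfp990, chosen after their values were seen, were split by genotype in the stimulated libraries but not in the resting ones. Their edgeR adjusted p in stimulated cells was 0.056, 0.0928 and 0.102, so they did not add to the 861 calls. Trim12a stood at 32.8 and 25.8 CPM in stimulated KO against 1.05 and 0.675 CPM in stimulated WT. At rest it stood at 0.475 and 69.3 CPM in KO and at 1.13 and 0.896 CPM in WT.

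Interferon response genes were lower in stimulated KO than in stimulated WT (median log2 fold change -1.89, SE over members 0.24, camera adjusted p = 2.28e-18, and adjusted p = 0.466 with an estimated correlation). The SE over members is that of a mean and treats the genes as independent. Their estimated correlation was 0.683, so this SE understates the uncertainty. Without stimulated WT 1 the median was -1.05 (SE over members 0.15), with 21 of 22 members below 0 and 2 passing, so that library could account for part of the size. Without stimulated WT 2 it was -2.41, with 18 passing. The median difference between both WT libraries was 1.39 and between both KO libraries 0.77, while stimulated WT 2 exceeded the KO libraries by 0.90 and 1.58 (log2 with a pseudocount of 0.1 CPM). Stimulated WT 1 was also the only stimulated library high in Xist, so its sex cannot be told apart from its other differences. By Xist, stimulated WT 2 and the KO libraries were of the same sex. A genotype effect and variation between mice or cultures cannot be told apart with 2 libraries in each group.

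Some genes were read in 1 library of a group and hardly in the other, with 60 genes of 11216 at 5 CPM or more and at least 8-fold apart within a pair (4 in stimulated KO, 10 in stimulated WT, 36 in resting KO and 31 in resting WT). Of these, 14 lay within 1 Mb of another (median 6 and highest 21 in 10000 random draws, permutation p = 0.02). Strain haplotypes that differ between the mice may account for part of them. The draws did not keep related neighbouring genes together, such as Trim5 and Trim12a. They therefore cannot tell haplotypes from other reasons for such genes to vary together. Another 10 were structured non-coding RNA genes, whose summed CPM was 254 in resting KO 2 and 238 in resting WT 1 against 13.4 in resting KO 1 and 9.98 in resting WT 2. Varying amounts of other cell types stay open, since 1 of the 60 was among their listed markers but the 11216 genes held only 31 of these, too few for that count to decide. Of the 60 genes 0 passed KO against WT in stimulated cells and 0 in resting cells by edgeR. Trim5, Trim12a, Trim30d and H2-Ea-ps, all among the 14 neighbours, passed KO against WT over both states by edgeR, and the groups of the design gave no biological explanation to test.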

How the results depend on the processing

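Thinning to the smallest library, leaving out the genes of chromosomes X and Y, and leaving out both resting libraries numbered 1 were tests chosen only after the data were seen. Counts within 1.5 times of the reported ones are not repeated here, and no direction of a named gene or list that had passed turned under any alternative run. The 46 genes of the resting genotype comparison became 323 with no filter on low counts, 463 by DESeq2, 14 by limma-voom, 7 with only the 4 libraries of the comparison and 27 without both resting libraries numbered 1. The 861 genes of the stimulated comparison became 1376 with no filter. The 40 genes that differed between states became 376 with no filter, 434 by DESeq2 and 14 without both resting libraries numbered 1. The 319 genes over both states became 611 with no filter, 194 with a stricter filter, 964 by DESeq2, 526 by limma-voom, 605 as the average of the 2 genotype contrasts, 197 with an absolute log2 fold change of at least 1 and 195 without both resting libraries numbered 1. With that fold threshold the state comparisons gave 7765 genes in WT and 7995 in KO, by construction. Leaving out 1 library at a time gave 2 to 38 genes at rest, 129 to 868 in stimulated cells, 8 to 91 for the difference between states, 1 to 309 over both states, 10130 to 12505 for stimulation in WT and 10142 to 12098 in KO, with the remaining library of a group assumed to vary like the other groups. Fewer libraries lower the power of these tests, and the cause of the other shifts was not tested. Scaling by library totals moved the median log2 fold change of all genes for stimulation in KO from -0.007 to 0.1. Of the 861 stimulated calls 760 were shared with DESeq2 and 810 with limma-voom. Depth limits the low counts, since a gene without counts gives only a bound against 3 counts over the group.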

Other observations

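The test of neighbouring genes was chosen only after the result was seen, and the split of the libraries was planned.

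Some genes of antibody switching and of plasma cells were uneven within 1 or both genotypes of resting cells. Aicda, chosen after its values were seen, stood at 229 CPM in resting KO 1 and 202 in resting WT 1, against 18.4 in resting KO 2 and 8.87 in resting WT 2. Ighg3, the IgG3 constant region, stood at 610 and 85.7 CPM in resting KO 1 and KO 2 and at 140 and 26.9 CPM in resting WT 1 and WT 2. Jchain, which joins IgM and IgA units, stood at 612 and 1795 CPM in the KO libraries and at 211 and 285 CPM in WT. The switching gene Ighg1 was more even, at 66.5 ± 16.9 CPM in resting KO and 14.0 ± 1.17 CPM in resting WT. Trim12a and Trim5, genes of antiviral factors chosen after their values were seen, were high in stimulated KO (32.8 and 25.8 CPM for Trim12a) and in resting KO 2 (69.3 CPM for Trim12a, 17.2 CPM for Trim5), and stood at 0.475 and 0.119 CPM in resting KO 1. Zfp990, a zinc finger gene also chosen after its values were seen, stood at 27.8 CPM in resting KO 1 and 56.9 CPM in resting WT 1, against 0.0405 CPM in resting KO 2 and 0.0853 CPM in resting WT 2.

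Genes called between stimulated KO and WT cells lay together on chromosome 9 from 40269217 to 44980431, where 15 of 50 neighbouring tested genes passed by edgeR, 2 higher and 13 lower. Among them were Cbl (-1.54), Bcl9l (-1.45), the adhesion gene Mcam (-3.71) and Cd3g, all but Cd3g chosen after their values were seen. In 1000 random orders of the genes the fullest window held a median of 9 and at most 14 (permutation p = 0.001, the smallest they can give). Of the 15 genes 11 had the same sign in resting cells, near the 68.6% of all 861 stimulated calls, and 1 passed there. A haplotype or regional difference between the mice may account for these 15 calls, a hypothesis found and tested on the same data.

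For KO against WT over both states, 1 of 34 splits of the 8 libraries into 4 and 4, the real one, gave as many genes, with 319 in the real split and 17 in the highest other. Only 18 of these splits hold 2 libraries of each state on each side, as the real one does, and the smallest share that those can give is 0.0556, too large for a share under 0.05. Without stimulated KO 2 the comparison gave 1 gene. The split equal to cell state could not be fitted.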
